A study of Homo sapiens with 6 samples.

How the data were processed

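Peak lists from 6 iCLIP libraries were analysed, made from Flp-In T-REx cells (HEK293 background) with an inducible, triple-Flag-tagged DUS3L, 3 from cells given 100 µM 5-FUrd for 12 h and 3 from cells without it. Per the labels' protocols, the treated libraries used 20 dishes and the control libraries 40, and no test here separates this from the treatment. By the same protocols, tetracycline (1 mg/mL) was added 12 h before the change of medium and kept afterwards, the protein was captured by anti-FLAG immunoprecipitation after RNase I digestion, and libraries were built with unique molecular identifiers. The labels do not say that the replicates came from separate cultures, so p-values of group comparisons measure the spread between these libraries, which may be technical. Tests of positions within a library take peaks as units and tests of gene lists take genes, so their p-values do not measure that spread. Per the submitters' processing notes, STAR and the GRCh38 build were used; the peak caller, its threshold and the treatment of multiply mapping reads are not given in the sources used here. Each library had its own lists. The deposited lists give for each peak a whole-number score from 10 to 4240, set by the authors; what it counts is not stated, and it was used only to rank or select peaks within a list. The lowest score was 10 in all 12 lists. Read totals were not used here, so the depth per library is unknown and no interval for a peak's level is given.

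The tRNA and rRNA lists name 210 tRNA reference sequences covering 328 tRNA names, some joined because they are identical. Of these names 311 were matched to a RefSeq tRNA gene, and 183 sequences had a single gene length without an intron and could be used for positions. Positions were counted back from 73 at the last base before CCA. The variable region was taken as 44 to 48 in tRNAs other than leucine, serine and selenocysteine, the D loop as bases 16 to 21 from the 5′ end, the anticodon arm as 27 to 43 and the T arm as 49 to 65. Gene lengths above 79 nt (95 nt for tRNAs with a long variable region) were taken to hold an intron. Peaks on the strand of the tRNA were used for counts of tRNAs and families and for positions; the tRNA share of the lists, the merged regions and the Jaccard index used both strands. The pre-rRNA reference was placed on chromosome 21 and divided by the RefSeq 18S, 5.8S and 28S genes.

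Regions were merged across lists where peaks on the same strand overlapped by at least 1 nt. A region or gene was called treated-only with a peak in all 3 treated and no control lists, and control-only the other way round. Peaks outside tRNA and rRNA were assigned to GENCODE release 29 genes on the same strand and to 11 classes in a fixed order: mitochondrial genome, snRNA, snoRNA, 7SL, 7SK, Y and vault RNA, microRNA, coding sequence, 3′ and 5′ untranslated region, other exon, intron, and no gene on the strand. Of 38 sequence names in these lists, 32 occur in that annotation. Distances to tRNA genes used the 443 nuclear tRNA genes of the RefSeq table.

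Group means were compared by exact two-sided permutation tests over 20 arrangements. Positions in tRNA were set against 10000 random placements of each peak within its own tRNA (one-sided). Sets of regions and genes and the Jaccard index over 15 pairs were compared over the 10 splits of the libraries. The 13 gene lists, written before the data were examined together with the main tests, were compared with the other genes that had a peak, by two-sided Fisher exact tests; 12 had a member with a peak. Named genes were chosen by a rule of the same date: up to 15 treated-only, 5 control-only and 10 genes in all 6 lists by median rank of their best score, up to 10 tRNA families of each kind, DUS3L, and members of gene lists with 10 or fewer genes with peaks, of which not every one is spelled out. The mitochondrially encoded genes MT-CO2, MT-TL1, MT-RNR2 and MT-TI fall outside this rule and were named after their values were seen. Named tRNA and rRNA sites, the counts near tRNA genes, the comparison of sense with antisense peaks, the shares among the best-scored tRNA peaks, and the strand test in genes were chosen after the data had been seen. Uridine content was planned on genome sequence, which was not used here; it was computed for peaks in exons of either strand with sequence from GENCODE transcripts.

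Alternatives were each library left out, the upper part of each list by score, lists of equal length, strand ignored, other overlap rules, a peak in 2 of 3 lists, other position rules, and differences within replicate numbers. A count-based test per region was not run because the score is not stated to be a count. The region counting was run on simulated data: of 200 treated-only regions placed among 8428, 199 were recovered, and 202 were called. Planted regions met the rule by design and the others were kept from meeting it, so this checks only the merging of peaks. No list repeated another, since at most 1.39% of lines were identical between lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.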

Results

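The series mapped RNA bound by DUS3L, a human enzyme that reduces uridine to dihydrouridine in RNA, in Flp-In T-REx cells, a derivative of the human embryonic kidney line HEK293 in which tetracycline switches on a transgene carried at a fixed site. Tagged DUS3L was induced in every culture, and the cells then grew for 12 h with or without 100 µM 5-fluorouridine (5-FUrd), a uridine analogue that cells build into RNA. The fluorinated base can trap uridine-modifying enzymes on their substrate as a covalent adduct, so that the enzyme carries its target through an anti-FLAG immunoprecipitation, and sites are then read by iCLIP (individual-nucleotide crosslinking and immunoprecipitation). Each group had 3 libraries, numbered 1 to 3, and each library had 1 peak list for tRNA and rRNA and 1 for the rest of the genome. The peaks were 2 to 5 nt wide. Each treated library started from 20 dishes of 10 cm and each control library from 40, so the amount of cells differs along with the treatment in every comparison below. The lists hold no read totals, so the depth of the libraries is unknown, and the number of libraries limits the precision. With 3 libraries against 3, an exact two-sided permutation test cannot give a p below 0.10, and that value marks groups without any overlap.

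The question of the main comparison was which RNA sites DUS3L occupies in a 5-FUrd-dependent way. Sense-strand tRNA peaks numbered 182 ± 7.09 (SD, n = 3) with 5-FUrd and 108 ± 19.5 (SD, n = 3) without it, 1.69 times as many (exact two-sided permutation p = 0.10). They lay on 148 ± 6.56 reference tRNAs from 46.7 ± 0.577 isoacceptor families with 5-FUrd, and on 91.7 ± 15.5 reference tRNAs from 37.0 ± 2.00 families without it (SD, n = 3 each, exact permutation p = 0.10 for both). An isoacceptor family is the set of tRNAs with the same amino acid and anticodon. In lists of equal length (207 peaks) the differences shrank to 5.33 reference tRNAs and 0.333 families (exact permutation p = 0.30 and 1.00). tRNA made up 55.1% ± 1.08 of all tRNA and rRNA peaks of both strands with 5-FUrd and 48.4% ± 4.55 without it (SD, n = 3 each, exact permutation p = 0.10), a difference of 6.71 percentage points that became 4.03 in lists of equal length (exact permutation p = 0.30). Sense rRNA peaks were closer between groups, at 102 ± 1.15 against 84.7 ± 6.11 (SD, n = 3 each, exact permutation p = 0.10).

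**Figure D1:**
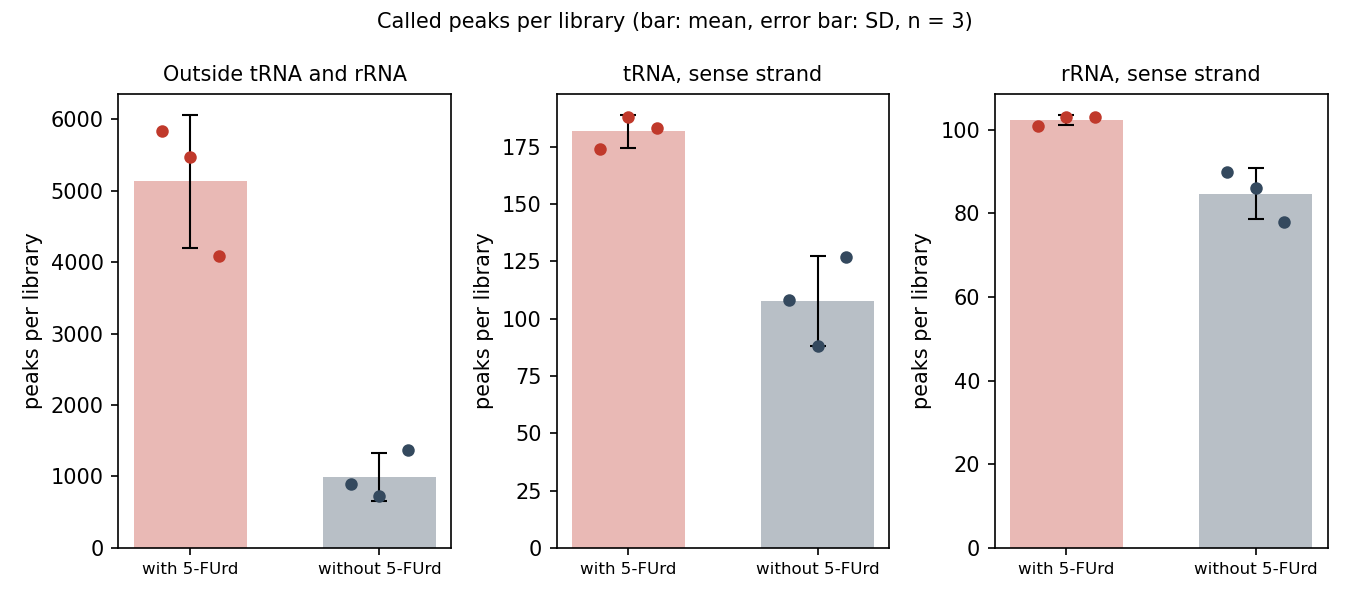
Peaks per library outside tRNA and rRNA, on the sense strand of tRNA and on the sense strand of rRNA. Points are libraries, bars are group means and error bars are SD (n = 3); the treated libraries hold 4081 to 5840 peaks outside tRNA and rRNA, above the control range of 725 to 1367.

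Of the 50 families with a sense peak in any list, 27 had a peak in all 6 libraries. By the rank of their best peak score in the treated lists, the leading families among these were Cys-GCA, Val-CAC, Thr-CGT, Val-AAC, the initiator iMet-CAT, Lys-TTT, Thr-AGT, Thr-TGT, Ala-AGC and Arg-TCT. Cys-GCA held the highest-scored peak of the tRNA and rRNA list in the treated libraries (median rank 1) and had a median rank of 90 in the controls, and Val-CAC stood at rank 2 against 43. Other families ranked higher in the control lists, among them Pro-TGG at 39 against 200, Arg-CCT at 3 against 24, Thr-TGT at 11 against 19 and Arg-TCT at 15 against 22. Because the lists differ in length, these ranks describe each list and do not measure a change. Ile-GAT, Gln-TTG, Glu-CTC, Leu-TAG and an asparagine tRNA listed without an anticodon had peaks in all 3 treated and no control libraries, with median best ranks from 273 to 376. These ranks lie beyond the end of the control lists, which held 207 to 253 peaks, so absence from the controls is weak evidence. No family had peaks in all 3 control and no treated libraries. How reads of near-identical tRNA copies were assigned is not given in the sources used here, so names of single tRNA genes are uncertain.

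Within tRNA, peaks of both groups gathered over the variable region, the short stretch between the anticodon arm and the T arm that contains position 47, where cytosolic tRNA can carry dihydrouridine. In tRNAs with a short variable region, 42.2% ± 3.75 of the sense peaks overlapped positions 44 to 48 with 5-FUrd and 42.5% ± 0.883 without it (SD, n = 3 each, exact permutation p = 0.90). This difference depended on the peaks used: it was 13.1 percentage points in lists of equal length and -5.75 with peaks of both strands (exact permutation p = 0.10 for both), against -0.309 here. Random placement of the same peaks within the same tRNAs put 9.90% to 10.3% there, and none of 10000 placements reached the observed share in any of the 6 libraries (p = 1e-04, the smallest they can give, one-sided permutation). Placement was uniform along the tRNA, though no library had a peak at positions 65 to 73 of these tRNAs. Random shares are therefore too low for peaks confined to the rest, and the placement tests at position 47 below share this limit. In the variable-region test, peaks on near-identical tRNA copies were counted separately, though such copies are not independent. Coverage was highest at position 45 with 5-FUrd (36.7% ± 2.97 of peaks) and at position 44 without it (36.5% ± 0.851; SD, n = 3 each). Position 47 itself was covered by 10.7% ± 1.36 of the sense peaks in all tRNAs with a known length with 5-FUrd and by 7.83% ± 0.524 without it (SD, n = 3 each, exact permutation p = 0.10). Against random placement, the share at position 47 was higher in treated libraries 1, 2 and 3 (one-sided permutation p = 0.0045, 0.0018 and 1e-04, adjusted over 6 libraries 0.0090, 0.0054 and 0.00060), while the controls gave p = 0.053, 0.16 and 0.059 (adjusted 0.071, 0.16 and 0.071). Counted once per family, the group difference at position 47 turned to -0.290 percentage points, and the placement test then also passed 0.05 in the 3 control libraries, as it did by peak midpoints within 2 nt (12.4, 13.2 and 15.5 points above random). In lists of equal length, treated library 1 no longer passed (3.65 points, one-sided permutation p = 0.11).

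**Figure D2:**
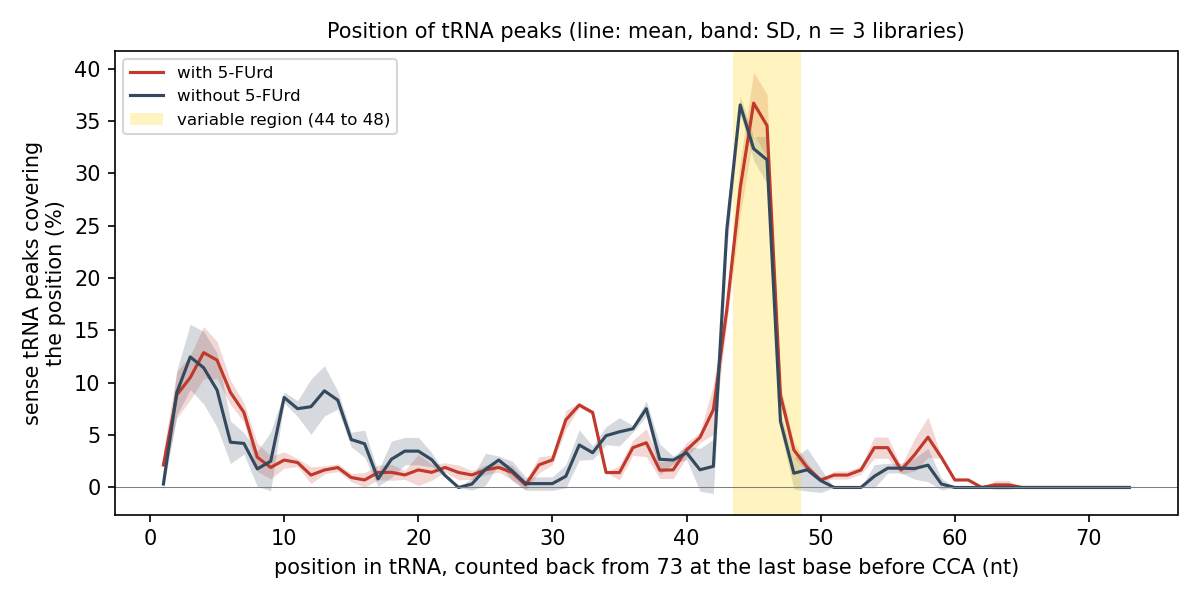
Percentage of sense tRNA peaks covering each position of tRNAs with a short variable region, counted back from 73 at the last base before CCA. Lines are means and bands are SD over 3 libraries; both groups peak at 44 to 46 (shaded: 44 to 48), both also rise at 2 to 6, and at 10 to 14 the controls are higher, with 9.23% at 13 against 1.67% with 5-FUrd.

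The groups parted in which tRNA sites scored best. Of the 50 best-scored sense tRNA peaks per library, 68.7% ± 7.02 lay over the variable region with 5-FUrd and 50.7% ± 1.15 without it. Of the 25 best, the shares were 88.0% ± 4.00 and 52.0% ± 4.00 (SD, n = 3 each, exact permutation p = 0.10 for both). The variable-region sites shared by all 6 lists were led, by rank in the treated lists, by Cys-GCA-14-1, Thr-CGT-1-1, Val-CAC-2-1, Val-AAC-5-1 and Val-CAC-4-1. Reproducible in the treated lists alone were variable-region peaks at 45 to 46 of Arg-TCG-2-1, Arg-TCG-5-1, Arg-TCG-4-1 and Arg-CCG-2-1, and anticodon-arm peaks at 29 to 33 of Ala-CGC-1-1 and 31 to 33 of the Val-CAC-1 group. Reproducible in the control lists alone were anticodon-arm peaks of Arg-CCT-4-1 (32 to 35) and Arg-TCG-3-1 (32 to 33), and peaks at 10 to 14 of the proline tRNAs Pro-AGG-1-1, Pro-CGG-1-1, Pro-CGG-2-1 and Pro-TGG-2-1. The same 10 to 14 site of Pro-TGG-3-4 (5 joined copies) had a peak in all 6 lists. Control-only sites also included Ala-TGC-1-1 at 43 to 44, which touches the variable region. Another was Arg-TCT-3-2 at bases 44 to 46 of its reference (median rank 15), without a counted position. The D loop, at bases 16 to 21 and the other place where tRNA carries dihydrouridine, was touched by 3.94% ± 0.801 of the peaks with 5-FUrd and 7.21% ± 2.61 without it. The T arm held 10.5% ± 1.35 of peak midpoints against 3.94% ± 2.60 (SD, n = 3 each, exact permutation p = 0.10 for both, the second 0.25 after Benjamini-Hochberg adjustment over 5 parts of the tRNA). The D loop difference of -3.27 percentage points was -1.77 without control library 1, -0.702 in the upper 50% by score and -5.49 in lists of equal length (exact permutation p = 0.20, 0.50 and 0.10). Counted by the best peak of each family, the variable-region share was 56.8% ± 5.72 against 46.8% ± 9.15, and the groups overlapped (SD, n = 3 each, exact permutation p = 0.20).

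**Figure D3:**
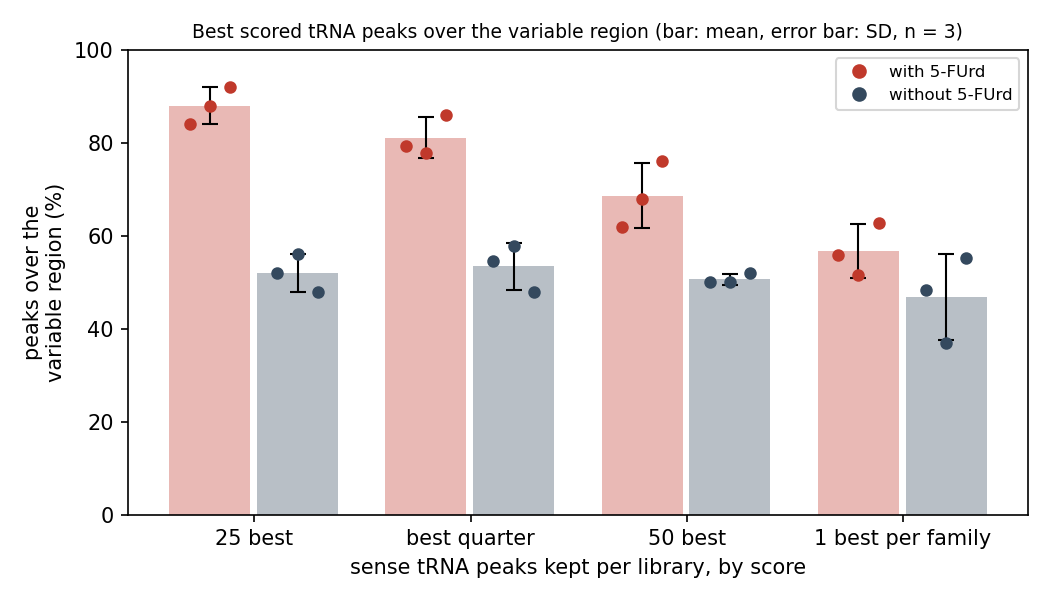
Share of the best-scored sense tRNA peaks of each library that overlap the variable region, for 4 ways of choosing the best peaks. Points are libraries, bars are means and error bars are SD (n = 3); the treated libraries lie at 84.0% to 92.0% among the 25 best peaks and the controls at no more than 56.0%.

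In the tRNA and rRNA lists, 159 regions had a peak in all 3 treated and no control libraries, 51 had a peak in all 3 control and no treated libraries, and 51 were in all 6, out of 810 merged regions. The 51 control-only regions became 86 without control library 3 and 12 with peaks within 50 nt joined. Of the treated-only regions, 55 were on the sense strand of tRNA, 42 on the sense strand of rRNA, 29 antisense to tRNA and 33 antisense to rRNA. The control-only regions held 16 sense tRNA, 31 sense rRNA and 4 antisense rRNA sites. Among rRNA sites, 28S rRNA had 14 sense regions in the treated lists alone and 15 in the control lists alone, and 18S rRNA had 6 and 3. The best-ranked treated-only rRNA site lay at nucleotides 1132 to 1136 of 18S rRNA (chromosome 21, 8438007 to 8438011, GRCh38, median rank 3), and the best-ranked control-only site at nucleotides 1146 to 1149 of 28S rRNA (chromosome 21, 8442291 to 8442294, median rank 1). With every list reduced to the 207 best-scored peaks, the length of the shortest, 64 regions were in all treated and no control lists and 55 in all control and no treated lists.

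Outside tRNA and rRNA, the libraries with 5-FUrd held 5129 ± 927 peaks and those without it 996 ± 333 (SD, n = 3 each, exact permutation p = 0.10), 5.15 times as many, covering 16624 ± 3132 nt and 2972 ± 1029 nt. Of 8428 merged regions, 1954 had a peak in all 3 treated and no control libraries, 91 in all 3 control and no treated libraries, and 267 in all 6. Without treated library 3 the treated-only regions were 3316, and without control library 3 the control-only regions were 142. Nuclear tRNA genes stood out in the control lists: 33.9% ± 6.88 of the control peaks lay in or within 100 nt of one, against 6.53% ± 1.31 of the treated peaks (SD, n = 3 each, exact permutation p = 0.10). The number of such peaks was 322 ± 36.6 without 5-FUrd and 327 ± 2.65 with it (exact permutation p = 0.80), so the excess of treated peaks lay elsewhere. Of the 91 control-only regions 70 were within 100 nt of a tRNA gene, and of the 1954 treated-only regions 54 were. The best-ranked control-only region was at chromosome 5, 181188430 to 181188432, at the valine tRNA gene TRV-AAC2-1. When every list was reduced to its 725 best-scored peaks, there were 174 treated-only and 167 control-only regions, 27 and 86 of them near a tRNA gene.

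Outside tRNA and rRNA, the mean Jaccard index (shared nt over covered nt) was 0.439 within the treated group, 0.386 within the controls and 0.0918 over the 9 pairs between groups, where the highest pair reached 0.136. For tRNA and rRNA the means were 0.541, 0.436 and 0.155. The lowest index within a group was 0.309 outside tRNA and rRNA and 0.377 in tRNA and rRNA, above the highest between groups in both cases (0.136 and 0.198). Lists of unlike length cannot reach a high index, which holds the values between groups down. In lists of equal length, the mean within groups exceeded that between groups by 0.292 outside tRNA and rRNA and by 0.339 in tRNA and rRNA.

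By annotation, most peaks outside tRNA and rRNA lay where GENCODE lists no gene on their strand: 68.6% ± 0.205 with 5-FUrd and 73.2% ± 1.03 without it. Introns held 25.1% ± 0.463 against 19.8% ± 1.85, coding sequence 2.04% ± 0.170 against 1.20% ± 0.162, and 5′ untranslated regions 0.962% ± 0.0591 against 0.449% ± 0.152. The mitochondrial genome took 0.217% ± 0.131 of the treated and 1.72% ± 0.346 of the control peaks (SD, n = 3 each; exact permutation p = 0.10 for all 5 classes, 0.14 after Benjamini-Hochberg adjustment over 11 classes). These are shares of lists that held 5129 ± 927 and 996 ± 333 peaks (SD, n = 3 each), so a gap in share need not be a gap in number. No class could pass 0.05 in this design. Without peaks near tRNA genes the differences fell from 0.839 to 0.341 percentage points in coding sequence (exact permutation p = 0.40) and from 5.36 to 3.48 in introns, and that outside genes went from -4.58 to -1.27, while the mitochondrial difference grew from -1.50 to -2.42 and the 5′ untranslated one from 0.513 to 0.629; in lists of equal length the 5′ untranslated difference turned to -0.0460. Treated peaks did not follow the strand of genes: of those in a gene of a single strand, 48.9% ± 0.270 lay on the gene's strand, against 55.3% ± 1.57 of control peaks (SD, n = 3 each, exact permutation p = 0.10).

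Of 2314 genes with a peak on their strand, 627 had one in all treated and no control libraries, 5 in all control and no treated libraries, and 86 in all 6. By median rank of the best peak in the treated lists, the leading treated-only genes were SMOC2, which encodes a matricellular calcium-binding protein (intron, chromosome 6, 168662946 to 168662950, rank 20), AKAP7, an anchoring protein for protein kinase A (intron, chromosome 6, 131181386 to 131181390, rank 69), and DHX37, an RNA helicase of ribosome assembly (intron, chromosome 12, 124972101 to 124972104, rank 145). Next came TULP4 and the overlapping AL360169.2, AL137230.2, CHCHD6, AK7, VPS13D, LINC00658, AC009779.4, MECOM, GABBR2, AL713999.1 and PLXNA1. Of these 15 genes, 14 had their best peak in an intron and VPS13D had it in coding sequence (chromosome 1, 12304656 to 12304658). The 5 control-only genes were USF2, MTUS2 and PANTR1, each with an intronic best peak, the mitochondrial glycine tRNA gene MT-TG (chromosome M, 10006 to 10007) and the minor-spliceosome snRNA gene RNU6ATAC (chromosome 9, 134164517 to 134164518). The genes in all 6 lists were led by LINC01962, KCTD2, AGBL5, AC084082.1, FMC1, LUC7L2, AC243772.3, CTNNBL1, CPNE4 and FBXO34. In all of these except CTNNBL1 and FBXO34 the best peak lay within 100 nt of a tRNA gene. The best peak of AGBL5, at TRY-GTA2-1, was itself a control-only region, while a region of AGBL5 near TRA-AGC8-1 was in all 6 lists. With every list at 725 peaks the numbers were 48 treated-only and 27 control-only genes, and without treated library 3 there were 1014 treated-only genes. The 5 control-only genes became 19 without control library 3 and 1 in the upper 50% by score.

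None of the fixed gene lists with a member in the data differed from the other genes in its share of treated-only genes (two-sided Fisher exact test, smallest p = 0.18, all 1.00 after Benjamini-Hochberg adjustment over 12 lists; of the other genes no more than 27.2% were treated-only). Of 16 mitochondrially encoded genes, MT-CO2 and MT-TL1 were treated-only, MT-TG was control-only, and MT-RNR2 and MT-TI had peaks in all 6 lists. Of 5 snoRNA genes with a peak (among them SNORD17, SNORD24, SNORD3A and SNORD43) and 4 spliceosomal snRNA genes (RNU12, RNU4-1, RNU4-2 and RNU6ATAC), none was treated-only and none had a peak in any treated list. Of 8 ribosomal protein genes, RPS29 was treated-only (3′ untranslated region), and the peak of RPL3 fell on a snoRNA gene inside it. In pyrimidine metabolism, DHODH, an enzyme of uridine synthesis, and DPYD, which degrades fluoropyrimidines, were treated-only, and RRM2 had peaks in 2 treated lists. Their scores were near the lowest score of 10: 46, 25 and 20 for DHODH, 19, 15 and 32 for DPYD, and 17 and 10 for RRM2. Because treated peaks did not follow the strand of genes, these and other treated peaks named here may not come from the gene's transcript. In the list of RNA uridine modifying enzymes, TRMT2A was treated-only at a microRNA gene within it, and PUS7 and NSUN2, a cytosine methyltransferase placed on the same list, each had a peak in 1 treated list. Of 7 translation factor genes, EEF1A2 and EIF2B1 were treated-only and EIF2AK3 was in all 6 lists, while EIF3E and EIF2D had peaks in 2 and 1 treated lists and EEF2 and EIF4A1 in 1 control list each. HSPA9, HNRNPAB and HIST2H2BF were treated-only in their lists, DNAJC8 and HIST1H4E had peaks in 2 treated lists, HNRNPA0 in 1 control list and FAS, of the p53 targets, in 1 treated list. Among 7SL, 7SK, Y and vault RNA genes, the copies RN7SKP119 and RN7SL834P were treated-only, and RN7SK, RN7SL2 and VTRNA1-2 had peaks in both groups. No tubulin or actin gene had a peak. DUS3L, whose transgene was induced in both groups, had no peak in any of the 6 lists.

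Base makeup could be read for peaks inside annotated exons. There, uridine made up 23.4% ± 1.24 of peak bases with 5-FUrd and 20.0% ± 1.81 without it, against 21.6% ± 0.626 and 23.5% ± 1.65 at places 100 nt to either side in the same transcript. The excess over the flanks was 1.84 ± 0.911 percentage points with 5-FUrd and -3.57 ± 2.78 without it (SD, n = 3 each, exact permutation p = 0.10). With places 200 nt away, the group difference of 5.41 points became 1.54 (exact permutation p = 0.40). The control values rest on 47 to 77 peaks per library and the treated ones on 373 to 514.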

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

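The tests of strand within genes, of treated-only less control-only regions, of rRNA antisense peaks (whole lists and equal length), of the best-scored tRNA peaks, including those by a share of the list, and of other splits were chosen after the values were seen; the tests with lists of equal length for treated-only regions and tRNA antisense peaks, of moved regions, of shared references and of families were fixed before theirs. For lists of equal length in tRNA antisense peaks and for shared references, the margin was changed after the values were seen: at first any gap above 0 between the groups, or no treated library past 10 points, was to count against the explanation, and both would have met that; the margin then had to exceed the spread, which leaves both open. The test of longer lists for the best-scored tRNA peaks replaced an earlier one that changed no value.

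Peaks on the strand opposite to tRNA drew attention because the report's tRNA counts and positions leave them out. They numbered 57.0 ± 4.00 with 5-FUrd and 5.67 ± 2.08 without it, or 23.9% ± 1.83 and 4.90% ± 0.890 of tRNA peaks (SD, n = 3 each, exact permutation p = 0.10). Antisense rRNA peaks did the same, at 92.3 ± 4.62 against 35.0 ± 5.57 (SD, n = 3 each, exact permutation p = 0.10). For rRNA, list length is argued against: in lists of equal length the antisense share was 47.2% ± 3.60 against 26.9% ± 5.79 (SD, n = 3 each), with 9.80 percentage points between the nearest libraries, against 11.9 in the whole lists. For tRNA it stays open: at equal length the antisense share was 9.57% ± 2.93 against 4.46% ± 0.270 (SD, n = 3 each), with 2.51 points between the nearest libraries, less than the treated SD. Copying of sense reads of the same tRNA also stays open: in the treated libraries antisense peaks lay on references with a sense peak 4.25 points more often on average than references in general did (95% t interval over the 3 libraries -10.1 to 18.6), and the test needed 10 to decide; the few control peaks gave 36.2, 63.8 and -0.952. A source common to both RNA kinds was not tested, since the gap of 11.9 points only restates the pattern.

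Outside tRNA and rRNA there were 1954 treated-only and 91 control-only regions. List length is argued against as the source of the separation of the groups, since lists of equal length held 174 treated-only regions, where no other split gave more than 16 in a direction. It stays open as the source of the excess over control-only regions: at equal length these numbered 167, which left a difference of 7, and lists of equal length leave little room for an excess. RNA of annotated genes read from its own strand is argued against as the whole source: of the regions in a gene of a single strand, 48.5% lay on the gene's strand (95% Wilson interval over regions 45.6 to 51.4). Of the regions in all 6 lists, 50.0% lay on the gene's strand (41.3 to 58.7), so this lack of preference was not particular to treated-only regions. Of the control-only regions 80.0% did (60.9 to 91.1), from 20 regions against 5. In lists of equal length the counts were 33 against 21 for control-only and 47 against 52 for treated-only regions. Since 70 of the 91 control-only regions lay within 100 nt of a tRNA gene, their strand need not reflect the transcript of the gene around them. Of the treated-only regions 62.1% lay inside a gene, against 60.3% of the same regions moved 100 kb to either side. The difference was 1.87 percentage points (95% interval over regions -1.18 to 4.93). A region moved this far can stay in the same long gene, such as MECOM (chromosome 3, 169083499 to 169663618). A small difference therefore cannot show that placement took no account of genes. A candidate explanation is reads placed at recurring sequences without regard to transcription, such as mismatched or very short inserts. Neither this nor a 5-FUrd-dependent source of such reads was tested.

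The best-scored tRNA peaks moved towards the variable region with 5-FUrd. A longer list is argued against, since among the best 25% of each library's sense tRNA peaks the lowest treated share was still 19.9 percentage points above the highest control share. A few families with several high peaks each may carry part of it: counted once per family, the lowest treated share was 3.66 points under the highest control share (a gap of -3.66). A 5-FUrd-dependent crosslink of DUS3L next to position 47 was not tested, since the gap of 10 points among the 50 best peaks is the pattern itself.

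Chance in the grouping of libraries was examined over all splits into 3 and 3. With 10 splits the share cannot fall under 0.05; in each case 1 of the 10 splits, the real one, gave the largest value. The real split gave 2045 regions outside tRNA and rRNA in both directions together (highest other 69), 210 tRNA and rRNA regions (highest other 6), 632 genes (highest other 19), and a within-group minus between-group Jaccard index of 0.321 outside (highest other 0.0290) and 0.333 inside tRNA and rRNA (highest other 0.0219).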

How the results depend on the processing

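The alternatives without peaks near tRNA genes or with both tRNA strands, and all alternatives of the uridine and best-peak results, were chosen after the data had been seen; the others were chosen before. Of 380 alternatives over 38 results, 327 did not reverse the direction, cross 0.05 or, for counts of regions, genes and gene lists, move by over 1.5 times. Differences in the numbers of peaks and tRNAs were not held to the 1.5 limit. The difference in peaks outside tRNA and rRNA, for one, went from 4133.67 to 2092 in the upper 50% by score. The 327 does not measure stability, since no 3 against 3 test could pass 0.05 and differences that fell to 0 are included: at equal length the difference in tRNA families went from 9.67 to 0.333 and in reference tRNAs from 56.3 to 5.33. The alternatives with replicate blocks, whose values could not change, are also included. Peaks outside tRNA and rRNA stayed more numerous with 5-FUrd (difference of group means 2092 to 4657.83), but these alternatives do not test it. Lists of equal length were not among them. A left-out library or a cut by score could not reverse ranges of 4081 to 5840 and 725 to 1367 peaks. The variable-region share of the best tRNA peaks stayed higher with 5-FUrd by 9.92 to 36 percentage points. Depth is unknown, so a missing control peak is weak evidence, and most changes below arise where lists lose peaks or libraries; other causes were not tested. Position 47 turned to -0.290 percentage points per family. The variable-region difference of -0.309 points was 1.53 per family, 13.1 in lists of equal length, 3.69 in the upper 50% by score and -5.75 with both strands, and -2.44 to 1.08 with a library left out. The 3′ untranslated difference of 0.0738 points turned to -0.0380 by bases and -0.291 in the upper 50%, and was -0.00647 to 0.186 with a library left out. The 5′ untranslated difference became -0.0460 in lists of equal length. The difference in other exons (-0.0704) became 0.552 in lists of equal length, 0.00699 in the upper 50% and 0.235 without peaks near tRNA genes.

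Treated-only regions outside tRNA and rRNA numbered 3874 with a peak required in 2 of 3 lists, 174 in lists of equal length, 1084 in the upper 50% and 1978 to 3316 with a library left out. Control-only regions numbered 204 with 2 of 3 lists, 167 at equal length, 40 with peaks within 50 nt joined, 21 without peaks near tRNA genes and 103 to 142 with a library left out. In tRNA and rRNA, treated-only regions were 270 with 2 of 3 lists, 64 at equal length, 100 joined and 99 in the upper 50%; control-only regions were 98 with 2 of 3 lists, 12 joined, 33 in the upper 50% and 51 to 86 with a library left out. Treated-only genes were 1183 with 2 of 3 lists, 48 at equal length, 1208 without regard to strand, 336 in the upper 50% and 635 to 1014 with a library left out. Control-only genes were 23 with 2 of 3 lists, 27 at equal length, 1 in the upper 50% and 6 to 19 with a library left out. With 2 of 3 lists, 1 gene list passed 0.05: mitochondrially encoded genes had fewer treated-only members than other genes (two-sided Fisher exact test, adjusted p = 0.0225). The excess at position 47 over random placement in treated library 1 was 3.65 points at equal length and no longer passed 0.05. In control libraries 1, 2 and 3 it passed per family (6.85, 6.55 and 8.67 points) and by peak midpoints within 2 nt (12.4, 13.2 and 15.5), in library 3 also at equal length (4.47), and in library 2 it was -0.861 in the upper 50%.

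Taking the replicate number as a block could not change the differences or the 1954 and 159 treated-only regions, which are the same by definition. Only the test changed. For the difference of 4133.67 peaks outside tRNA and rRNA, the two-sided exact sign-flip p was 0.25, the smallest that 3 pairs can give. Same-numbered libraries did not deviate together in the ranks of shared regions (correlations -0.241, -0.133 and -0.222 outside, -0.0763, -0.341 and -0.223 inside tRNA and rRNA), so the numbers do not pair them. Left out were a count-based model per region, uridine on genome sequence, cytosolic tRNA alone (the tRNA lists held no mitochondrial tRNA) and leave-one-out for placement tests within a library.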

Other observations

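Peaks were on average 3.24 ± 0.0291 nt wide with 5-FUrd and 2.98 ± 0.0393 nt without it outside tRNA and rRNA (SD, n = 3 each). Antisense tRNA peaks, 31 of them in all lists together, reached up to 3 nt past the gene end, and no sense peak did.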
